A study of Homo sapiens with 8 samples.

How the data were processed

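Expression was measured on 8 Affymetrix human arrays hybridised with biotinylated cRNA from HTETOP cells, a human line derived from HT1080 fibrosarcoma cells in which topoisomerase II alpha is under tetracycline control. The labels place 1 array in each of the doxycycline and doxycycline vehicle groups, and 3 arrays in each of the dexrazoxane and dexrazoxane vehicle groups. Doxycycline was given at 1 µg/ml and dexrazoxane at 100 µM, each for 24 h. Every array carried RNA pooled from 3 passages, per the labels, which number those of the doxycycline pair 15 to 17. The labels do not say whether the numbered arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

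The deposited table holds log2 expression values per probe set made with RMA, per the submitters' processing notes. RMA corrects background, makes the intensity distributions of arrays alike and summarises the probes of a set. Whether all arrays went through it together is not given in the sources used here. The medians of the doxycycline pair were 4.82 and 4.81 and those of the other 6 arrays ran from 5.49 to 5.57, so levels were not compared between the 2 treatments, except in 1 alternative, in the correlations between arrays and in 1 comparison of TOP2A in the closing section. In the doxycycline pair 5261 of 54675 probe sets (9.62%) had identical values on both arrays, against 6 to 42 between any 2 of the dexrazoxane and dexrazoxane vehicle arrays. The number of arrays limits the precision of every value.

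Probe sets were named through the platform annotation supplied with the data. Of the probe sets, 41097 carried 1 gene symbol, 1801 carried several and 11777 were not named there; only those with 1 symbol were used. Symbols of 41043 probe sets were brought up to date through Entrez identifiers and a RefSeq gene table of assembly GRCh38.p14, and 54 kept the annotation's symbol. The probe set with the highest mean over the 8 arrays stood for its gene, which gave 19775 genes. A gene was tested if that mean reached the 40th percentile of all probe sets, a log2 value of 4.83, which left 14731 genes. Gene lengths were the spans in the same gene table.

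Dexrazoxane and vehicle were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the genes tested, 0.05 as the bound). The fit planned before the data were examined had no block. The labels share the numbers 1 to 3 between the groups, and the numbers were then checked. Deviations from the group means correlated at 0.823, 0.574 and 0.716 between arrays of the same number and at -0.629 to 0.181 between arrays of different numbers. Deviations sum to 0 within a group, so high values for same-numbered arrays push the others down and the contrast is not separate evidence. So few arrays can be matched in few ways, and the numbered match could be the best by chance. Same-numbered arrays were taken as pairs on this check, and a second fit held the replicate number as a block. The calls of that fit rest on a pairing checked in the same data. Both fits give the same mean differences; the standard errors printed here come from the paired fit.

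The 25 gene lists held 454 genes taken from general knowledge, of which 372 were tested; the rest were below the filter or had no probe set annotated to them alone in the table used. Lists were tested with camera at a preset inter-gene correlation of 0.01, with the correlation estimated, and with fry. For the single doxycycline pair no p-value was computed. The median difference of each list was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and called outside when it lay under the 2.5th or over the 97.5th percentile.

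Named genes followed a fixed rule. For dexrazoxane it took the 10 largest rises and the 10 largest falls among genes at an adjusted p under 0.05 whose 3 treated arrays all lay on one side of the 3 vehicle arrays, and for each list up to 4 members with the smallest p in the fit without the block. Because that fit called 0 genes, the rule for the largest changes was applied to the paired fit. For doxycycline it took the 10 largest rises and falls among tested genes whose higher array reached the median of all probe sets, and up to 3 members with the largest difference in each list described. TOP2A and TOP2B were always named, and unnamed transcripts were passed over. One gene that the rule takes from the repair list is not reported here.

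The procedure was tested on simulated arrays built from the dexrazoxane data, over 14731 genes with 200 changed genes in each of 5 draws. For the dexrazoxane comparison the paired fit recovered 30.7% of genes changed by 0.5 on the log2 scale, 81.8% of those changed by 1 and 99.4% of those changed by 2, with 2.8 false calls per draw on average. The fit without the block recovered 0%, 61.4% and 97.0%, with 0 false calls. Each simulated array was the mean of its same-numbered pair plus independent normal noise at the residual SD of the paired fit. The pairing was thus built in, so these rates cannot tell whether the numbers mark pairs.

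Alternatives were another quantile normalization, centring each array on its median, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, probe sets without cross-hybridising suffixes, every probe set on its own, trended and robust variance, the replicate block, leaving out each array or pair, other list tests, a 1.5-fold bound, and the 3 dexrazoxane vehicle arrays as comparator for doxycycline.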

Results

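The arrays recorded the transcripts of HTETOP cells after 24 h with doxycycline, which silences TOP2A in this line, or with dexrazoxane, a bisdioxopiperazine that blocks the catalytic cycle of topoisomerase II. The doxycycline pair comprised 1 treated and 1 vehicle array, and the dexrazoxane comparison 3 treated and 3 vehicle arrays. The design asks which transcripts change when TOP2A expression is shut off and which change with an inhibitor of topoisomerase II, which is not limited to TOP2A. Control probe sets for the 3' and 5' ends of ACTB differed by -0.04 to 0.11 (log2) over the 8 arrays, and those of GAPDH by -0.10 to -0.02.

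TOP2A, the topoisomerase that untangles replicated chromosomes, was 62.1-fold lower on the doxycycline array than on its vehicle array, with log2 values of 6.02 and 11.98 for the probe set that stood for the gene (201291_s_at). A second TOP2A probe set (201292_at) was 12.5-fold lower, at 5.88 against 9.52. Another (237469_at) had a mean under the filter, with a difference of 0.06. TOP2B, which encodes the other type II isoform, differed by -0.06. There are no replicates in this comparison, so none of its differences has an error.

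TOP2A also fell under dexrazoxane. Its mean log2 value was 12.45 ± 0.086 (SD, n = 3) with vehicle and 10.88 ± 0.339 (SD, n = 3) with dexrazoxane, a difference of -1.57 ± 0.12 (SE) or 2.97-fold, and it was lower in each of the 3 pairs, by -1.21, -1.63 and -1.88. The limma adjusted p was 0.0043 in the paired fit and 0.0949 without the block. The second probe set fell by 1.76 on the log2 scale (3.38-fold). When all 41097 probe sets with 1 symbol were tested without the filter, its limma adjusted p was 0.0018 paired and 0.0315 without the block. In that same test the first probe set had limma adjusted p of 0.0231 and 0.152. TOP2B differed by -0.13 ± 0.08 (SE, limma paired adjusted p = 0.373).

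**Figure D1:**
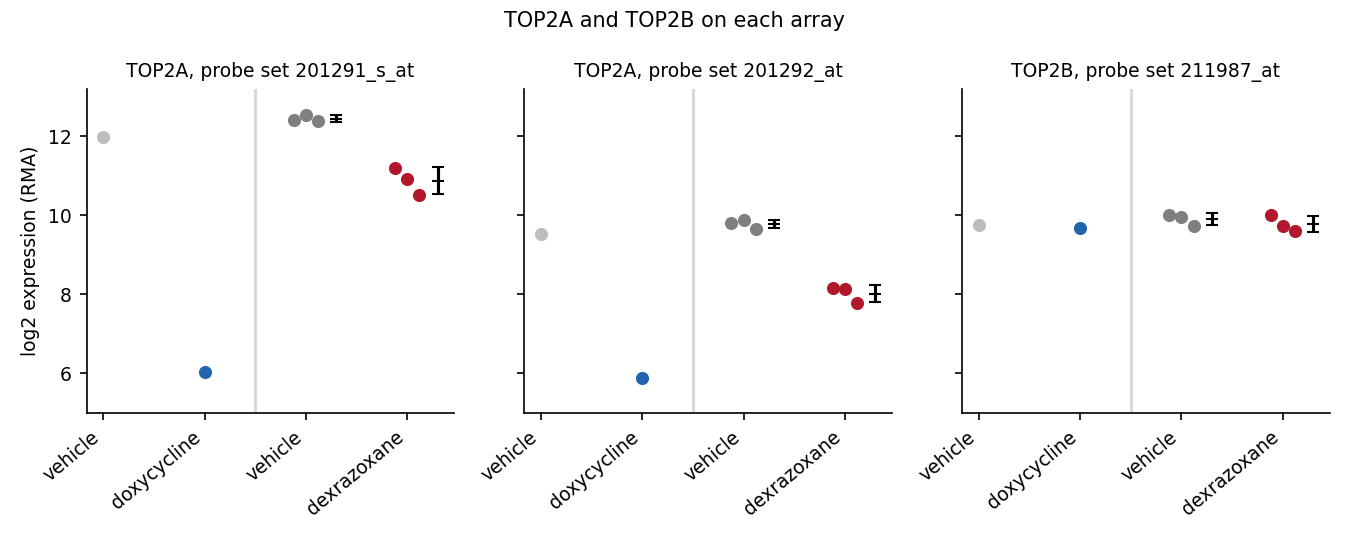
Log2 expression (RMA) of the TOP2A probe sets 201291_s_at and 201292_at and of the TOP2B probe set 211987_at on each of the 8 arrays, with each point an array and bars the mean and SD of 3 arrays; the vertical line parts the doxycycline pair from the dexrazoxane comparison. TOP2A lies at 6.02 and 5.88 on the doxycycline array, against 11.98 and 9.52 on its vehicle array. With dexrazoxane it averages 10.88 and 8.02, against 12.45 and 9.78 with vehicle. TOP2B lies at 9.69 with doxycycline and 9.75 on its vehicle array, and between 9.60 and 10.02 on the other arrays. Levels are to be read within each comparison, not across the line.

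Among genes called in the paired fit whose 3 treated and 3 vehicle arrays did not overlap, the largest rises with dexrazoxane were in ATF3, a stress-induced transcription factor (1.29 ± 0.08 on the log2 scale, SE, n = 3 pairs, 2.44-fold), in SERPINI1, which encodes neuroserpin (1.10 ± 0.09), and in TP53INP1, a p53-induced nuclear protein gene (1.04 ± 0.15). They were followed by CYP4F3, a fatty acid omega-hydroxylase (0.96), the chaperone gene DNAJB2 (0.93), FKBP1B, which encodes a binding protein of ryanodine receptors (0.93), PPL, which encodes the desmosomal and cornified envelope protein periplakin (0.90), the p53-inducible oxidoreductase TP53I3 (0.89), the small GTPase gene ARL14 (0.87) and the late cornified envelope gene LCE1B (0.82). After TOP2A, the largest falls among such genes were in KCNMA1, the pore-forming subunit of the large-conductance calcium-activated potassium channel (-1.07 ± 0.11), in ROR1, a receptor tyrosine kinase-like receptor for WNT5A (-1.02 ± 0.09), and in TENM2, a teneurin adhesion molecule (-0.97 ± 0.09). TMEM132D (-0.90), SHROOM2, which organises apical actin (-0.89), the potassium channel gene KCNU1 (-0.89), the hyaluronan synthase gene HAS2 (-0.86), the anion exchanger gene SLC26A4 (-0.84) and the formin gene FMNL2 (-0.84) came next. These 20 genes had limma paired adjusted p-values of 0.0022 to 0.0175. Their single direction in 3 of 3 pairs follows from the rule that picked them and is no added support. Of the 10 falls 7 were in genes spanning over 100 kb, and of the 10 rises 0. For scale, of the 14712 tested genes with a known length 1524 spanned 100 to 200 kb, 699 spanned 200 to 400 kb and 315 spanned more.

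The paired limma fit called 357 genes higher and 360 lower with dexrazoxane, with a median absolute log2 difference of 0.43. At least 2-fold changes were called for 7 genes. Of these ATF3, SERPINI1 and TP53INP1 were higher and TOP2A, KCNMA1 and ROR1 lower; the seventh, MMP12, a macrophage metalloelastase gene named after its value was seen, rose by 1.37 ± 0.15. The limma fit without the block called 0 genes in either direction, with 765 at an unadjusted p under 0.05 where chance gives 737, and a lowest adjusted p of 0.0949. Treated and vehicle arrays did not overlap for 10.1% of all genes tested, where chance gives 10%. Among the 717 genes called in the paired fit they did not overlap for 364 (50.8%), and the rest overlapped. When each array was centred on its median the paired fit called 244 higher and 467 lower. Without pair 1 the paired fit called 42 higher and 56 lower.

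**Figure D2:**
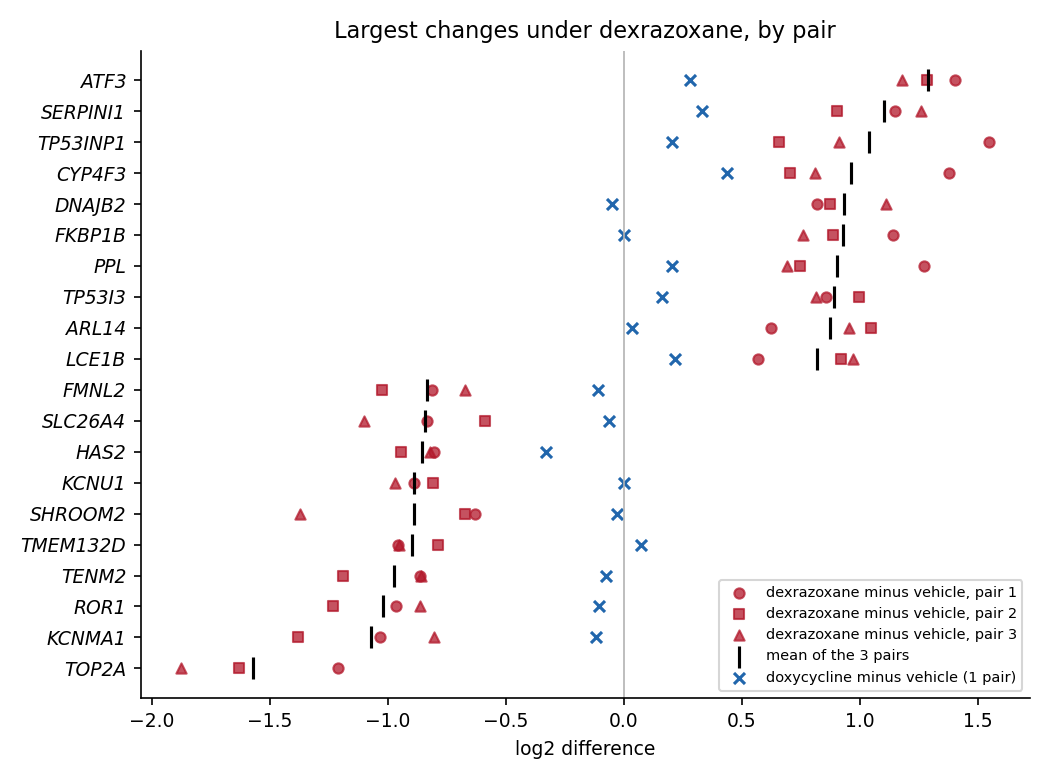
Log2 difference between dexrazoxane and vehicle in each of the 3 pairs (red symbols) and their mean (black bar) for the 10 largest rises and 10 largest falls among called genes whose treated and vehicle arrays did not overlap, with the doxycycline minus vehicle difference of the single pair as a blue cross; the cross of TOP2A, at -5.96, is beyond the axis and not drawn. All red symbols of a gene lie on one side of 0, as the selection requires, with means from 1.29 for ATF3 to -1.57 for TOP2A.

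Of 26 tested genes induced by p53, 11 rose and 0 fell with dexrazoxane in the paired fit (16 and 0 adjusted over the list alone, and 6 and 0 without the block), with a median of 0.29 and 24 members above 0. Beside TP53INP1 and TP53I3 these included MDM2, the ubiquitin ligase that degrades p53 (0.58 ± 0.08), and DDB2, a damage recognition factor of nucleotide excision repair (0.45 ± 0.08). Camera with the preset correlation gave an adjusted p of 1.56e-12 without the block and 2.62e-10 paired; with an estimated correlation the adjusted p was 0.635 and 0.757. MDM2 lost its call with the mean of its probe sets (0.31, limma paired adjusted p = 0.0633) and with specific probe sets (0.41, 0.0552).

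Among 30 tested G2/M and mitosis genes 19 fell and 0 rose (27 and 0 adjusted over the list alone, and 0 and 0 without the block), with a median of -0.39. They included CCNB1, the cyclin that drives entry into mitosis (-0.40 ± 0.07), HMMR, a spindle-associated protein gene (-0.60 ± 0.09), the centromeric histone gene CENPA (-0.38 ± 0.08) and the spindle checkpoint kinase gene TTK (-0.60 ± 0.08). Among 24 G1/S and replication genes 17 fell and 0 rose (20 and 0 adjusted over the list alone, and 0 and 0 without the block), with a median of -0.48. RRM2, a subunit of ribonucleotide reductase, fell by 0.52 ± 0.08, the replication factor genes GINS1 and CDC45 by 0.56 ± 0.08 and 0.60 ± 0.12, and the origin licensing gene CDC6 by 0.58 ± 0.08. Camera gave adjusted p-values of 3.64e-16 for the first list and 7.14e-12 for the second without the block, and 3.16e-21 and 3.28e-17 paired. With an estimated correlation the adjusted p was 0.635 for both without the block, and 0.575 and 0.757 paired.

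Of 15 homologous recombination and Fanconi anaemia repair genes 7 fell and 0 rose (12 and 0 adjusted over the list alone, and 0 and 0 without the block), with a median of -0.33. The checkpoint kinase gene CHEK1 fell by 0.44 ± 0.08, the exonuclease gene EXO1 by 0.62 ± 0.09, and FANCI, a clamp subunit of the Fanconi pathway, by 0.63 ± 0.08. Camera gave an adjusted p of 6.51e-08 without the block and 4.02e-10 paired, and with an estimated correlation the adjusted p was 0.635 and 0.625. Without pair 1, CHEK1, EXO1, RRM2, CDC45, CDC6, CCNB1, CENPA, MDM2 and DDB2 kept their direction but not their calls (limma paired adjusted p of 0.0624 for EXO1 to 0.140 for CENPA). Calls were also lost for CENPA without pair 2 (0.0578) and with no filter (0.0581), for CHEK1 and CCNB1 without pair 3 (0.0765 and 0.0925), and for DDB2, CHEK1, CDC45, CCNB1 and CENPA with every probe set on its own (0.0531 to 0.0704).

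**Figure D3:**
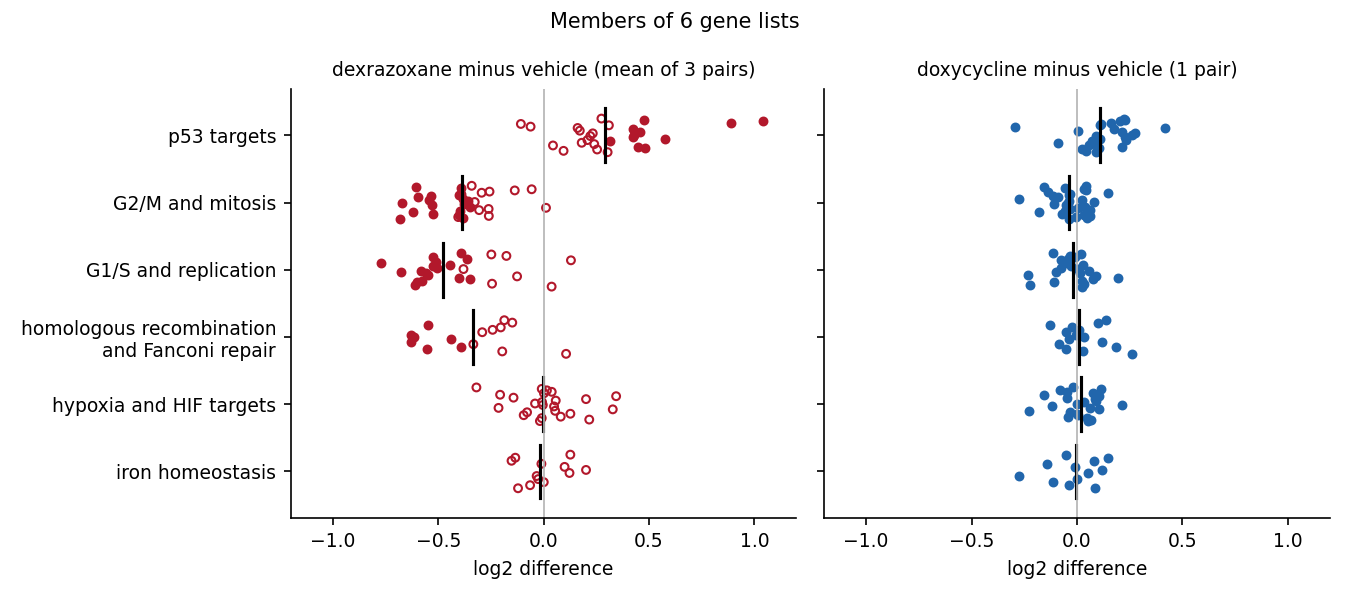
Log2 difference from vehicle of the tested members of 6 gene lists, as the mean of 3 pairs for dexrazoxane (left; filled points have a paired adjusted p under 0.05) and for the single doxycycline pair (right; no test), with each point a gene and the black bar the median. Under dexrazoxane the medians are 0.29 for p53 targets, -0.39 for G2/M, -0.48 for G1/S and -0.33 for recombination genes, and no member of the hypoxia and iron lists is filled.

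The other 21 lists did not pass camera (adjusted p of 0.123 to 0.961 without the block and from 0.184 upwards paired), although single members changed. Dexrazoxane is hydrolysed to an iron chelator, and neither of the lists that answer to iron held a called gene: 0 of 12 iron homeostasis genes and 0 of 24 hypoxia and HIF target genes, with medians of -0.02 and -0.001. Adjusted over the list alone, 2 hypoxia genes were higher and 1 lower. In the ATF4 and integrated stress response list ATF3 rose and SLC7A11, the cystine transporter gene, fell (-0.59 ± 0.10), with 20 of 22 members not called. Among 16 immediate early genes ATF3 and JUND (0.44 ± 0.08) rose and MYC fell (-0.51 ± 0.09). Among 17 extracellular matrix and TGF-beta targets, THBS1, which encodes thrombospondin-1, and CCN1 fell by 0.61 ± 0.07 and 0.35 ± 0.07, and the stromelysin gene MMP3 rose by 0.74 ± 0.09. ISG15, a ubiquitin-like modifier, rose by 0.64 ± 0.08 as 1 of 18 interferon response genes, and the histone gene H4C8 rose by 0.51 ± 0.07 as 1 of 13 core and linker histone genes. Of 13 NRF2 and oxidative stress genes OSGIN1 rose (0.37 ± 0.08) and SLC7A11 fell. TOP2A was the 1 called gene of 6 topoisomerases. Adjusted over the list alone, the counts higher and lower were 3 and 3 for the ATF4 list, 3 and 1 for immediate early genes, 1 and 5 for matrix genes, 2 and 0 for interferon genes, 1 and 3 for histones, 2 and 2 for NRF2 genes and 0 and 1 for topoisomerases.

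No member was called in the paired fit among 16 apoptosis and BCL2 family genes, 15 NF-kB and inflammatory genes, 15 cholesterol synthesis genes, 18 respiratory chain genes, 19 mitochondrial translation genes, 18 glycolysis genes, 9 heat shock genes and 11 cytosolic ribosomal protein genes. The same held for the markers of cell types, with 11 mesenchymal, 6 epithelial, 6 leukocyte and 5 endothelial genes tested. Adjusted over the list alone, 1 mesenchymal gene was higher and 2 were lower, and the other lists of this paragraph held 0 calls. Medians of the 21 lists lay between -0.09 and 0.12. Median, mean and camera direction without the block differed in sign for the hypoxia, iron, NF-kB, ATF4, glycolysis, heat shock and NRF2 lists.

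In the doxycycline pair TOP2A and FAM30A (-1.03) were the 2 genes at least 2-fold lower, and 0 were at least 2-fold higher. FAM30A was dim, at 4.91 on the vehicle array and 3.88 on the doxycycline array, whose median was 4.81. At 1.5-fold there were 4 higher and 15 lower genes. The SD of the log2 differences over all genes was 0.146. For scale, pairs of arrays of the same dexrazoxane or vehicle group held 12 to 206 genes at least 2-fold apart, with SDs of 0.221 to 0.370, and the 3 pairs of dexrazoxane and vehicle arrays held 12, 43 and 15, with SDs of 0.210 to 0.257. The doxycycline pair had 9.62% of its probe sets at identical values and is not known to have been normalized with the other arrays, so its SD and counts are not directly comparable with theirs. The genes named next were picked among those whose brighter array reached the median of all probe sets, with unnamed transcripts passed over. Some genes past 1.5-fold are therefore not named. Other than TOP2A the picked genes were dim. Their log2 values on the brighter array were 4.89 to 6.41 for the positive and 4.83 to 5.85 for the negative differences, with the lower ends bounded by that rule. KIR3DL3, a killer cell receptor gene, differed by 0.81, GCNA by 0.66, FTX by 0.64, PSLNR and SLC26A11 by 0.54, HOXB8 by 0.53, and KCNMB1, WT1-AS, ACER2 and KEL by 0.49. After TOP2A and FAM30A the largest negative differences among the picked genes were those of FBLN7 (-0.68), TMEM253 (-0.66), ZSCAN1 (-0.65), LINC02012 (-0.60), TENT5B (-0.60), PSG6 (-0.58), PRB1 (-0.56) and FBXW10B (-0.55).

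In the doxycycline pair the p53 target list had the highest percentile of the 25 lists. Its median was 0.112, with 24 of 26 members above 0, at percentile 100 of matched random lists, which ran from -0.013 to 0.060 between their 2.5th and 97.5th percentiles. Its largest differences were those of SESN2, a stress-inducible sestrin gene (0.42), SPATA18 (-0.30) and the translesion polymerase gene POLH (0.27). The ATF4 list (median 0.083, percentile 99.7) was led by SESN2, ATF3 (0.28) and PPP1R15A (0.21), and the glycolysis list (0.048, percentile 98.2) by SLC2A1 (0.12), ENO2 and SLC2A3 (0.10 and -0.10). Below the random lists lay the G2/M list (-0.036, percentile 0.03), with ECT2 at -0.27, CCNA2 at -0.18 and TTK at -0.16, the G1/S list (-0.019, percentile 0.93), with E2F8 at -0.23, CCNE2 at -0.22 and CLSPN at 0.20, and the interferon list (-0.062, percentile 1.3), with IFIH1 at 0.27, USP18 at -0.27 and IFIT2 at -0.24. Members below 0 numbered 18 of 30 for the G2/M list, 13 of 24 for G1/S and 10 of 18 for interferon. The interferon median turned to 0.05 with the filter at the 60th percentile and to 0.03 with the mean of probe sets. The other 19 lists, repair, iron and hypoxia among them, lay inside those bounds. The random lists do not hold the correlation between members of a list, so no p is given. Against the 3 dexrazoxane vehicle arrays, where the median of all genes shifted by -0.49, the medians were -0.47 for the p53 list, -0.65 for ATF4, -0.51 for glycolysis, -0.09 for G2/M, 0.01 for G1/S and -0.84 for interferon.

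TOP2A was the 1 gene at least 2-fold lower in both comparisons. Across the 14731 genes the doxycycline difference correlated with the mean dexrazoxane difference at 0.233 (Pearson; Spearman 0.248), and at 0.222 and 0.248 without TOP2A. Genes are not independent replicates, so no p is given. The same correlation against the 6 differences between arrays of one dexrazoxane or vehicle group ran from -0.154 to 0.160. By pair it was 0.354 for pair 1, 0.095 for pair 2 and 0.123 for pair 3. Of the 357 genes called higher with dexrazoxane 288 (80.7%) were also above 0 with doxycycline, against 54.3% of genes not called; of the 359 lower genes other than TOP2A 228 (63.5%) were below 0, against 40.8%. ATF3, TP53INP1, SERPINI1 and CYP4F3, which rose with dexrazoxane, differed by 0.28, 0.20, 0.33 and 0.44 with doxycycline, and HAS2 by -0.33. KCNMA1, ROR1 and TENM2 differed by -0.12, -0.10 and -0.07. DNAJB2 (-0.05) and TMEM132D (0.07) had the opposite sign with doxycycline, and FKBP1B and KCNU1 had a difference of 0.

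**Figure D4:**
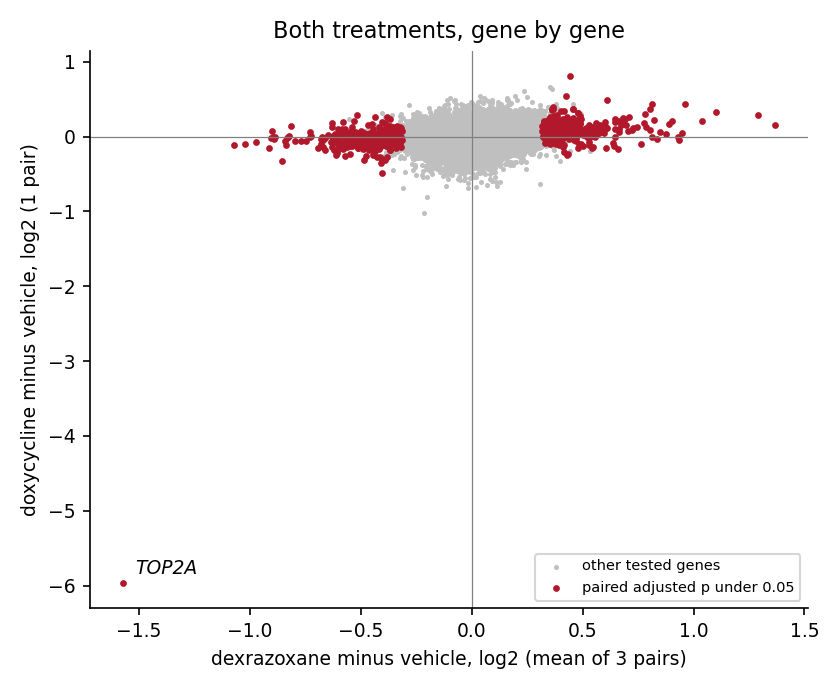
Doxycycline minus vehicle log2 difference of the single pair (vertical axis) against the dexrazoxane minus vehicle log2 difference, the mean of 3 pairs (horizontal axis), for the 14731 genes tested; red points have a limma paired adjusted p under 0.05. TOP2A stands apart at -1.57 and -5.96, and the correlation over all genes is 0.233.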

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

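Alternatives with the block were chosen after seeing the data, as were the correlations by pair. With the replicate block, dexrazoxane calls went from 0 higher, 0 lower and 0 at 2-fold to 357, 360 and 7. Without it, 1 lower gene and 1 at 2-fold were called with specific probe sets, with every probe set on its own and with trended, robust variance, and 0 to 1 when 1 array was left out. Camera called 4 lists, 4 to 10 with 1 array left out (10 without vehicle replicate 1), and 0 with an estimated correlation or with fry for direction, with or without the block. Fry for either direction called 13 lists with the block.

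In the paired fit no filter gave 195 higher and 230 lower genes, the 60th percentile filter 553 higher, every probe set 164 higher, trended and robust variance 992 and 852, and the mean of probe sets 3 at 2-fold. Fewer or more genes tested change the adjustment; the cause of the other shifts was not tested. Leaving out a pair gave 42 to 416 higher and 56 to 414 lower genes and 8 to 13 at 2-fold. Of 382 values of named genes in the paired fit under alternatives 362 kept their direction and side of the threshold and 20 lost the call.

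The 2 doxycycline genes at 2-fold became 1 (TOP2A) after another quantile normalization, with the 60th percentile filter and with the mean of probe sets, and 19 at 1.5-fold. Against the 3 dexrazoxane vehicle arrays they became 1599, with a median shift of -0.49 that reflects the different array levels, and 10 lists lay outside, against 6 in the main comparison and 4 to 7 under the other alternatives. The correlation between treatments was 0.356 over called genes, 0.354, 0.0948 and 0.123 by pair, and 0.124 to 0.304 with 1 array left out. Against those shared vehicle arrays it was 0.0573 (covariance 0.00396). Simulated unchanged arrays gave 0.353 (covariance 0.0182), but they were independent, without the likeness of same-numbered arrays. The simulated value is therefore no yardstick for the observed one. The dexrazoxane differences of the 35 genes followed under the alternatives kept their sign. Against the 3 dexrazoxane vehicle arrays the 10 positive doxycycline differences picked by the naming rule, other than that of PSLNR, turned negative. The doxycycline medians of the p53, ATF4 and glycolysis lists turned negative there too, and that of the G1/S list turned positive. The interferon median turned positive with the 60th percentile filter and with the mean of probe sets.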

Other observations

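Other than the counts of splits, the tests below were chosen after the result was seen. The genes that fell under dexrazoxane were often very long. Of the 358 genes called lower in the paired limma fit that had a known length 75 (20.9%) spanned over 200 kb, against 8 of the 357 called higher (2.24%) and 6.89% of the 14712 tested genes with a known length. The share called lower was 0.926% of genes under 10 kb, 2.03% at 10 to 50 kb, 3.54% at 50 to 100 kb, 2.82% at 100 to 200 kb, 6.29% at 200 to 400 kb and 9.84% above 400 kb. Of 40 genes lower by at least 0.5 in every pair 13 were over 200 kb, against 0 of 37 genes higher by as much. They were the channel gene KCNMA1, ROR1, TENM2, TMEM132D, FMNL2, SORBS2, ADAMTS6, which encodes an extracellular protease, the heparan sulfate genes EXT1 and GPC6, the metalloproteinase gene PAPPA, the growth factor gene PDGFC, the ephrin gene EFNA5 and POLA1, the catalytic subunit of DNA polymerase alpha; those from SORBS2 on were named after their values were seen.

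The median difference was -0.07 for 1014 genes over 200 kb and 0.02 for the rest, a small shift found on these arrays. Low expression of long genes is argued against, since their median lay at percentile 0 of random lists matched on mean level. A length gradient between arrays stays open: the pairs shifted by -0.0682, -0.139 and -0.0736, and their differences correlated with length at -0.0199, -0.237 and -0.139 (Spearman), so pair 1 barely followed length over all genes, while arrays of one group, which always differ in number too and are no exact yardstick, shifted by up to 0.106 and correlated at up to 0.234. Loss of TOP2A alone stays open too. In the single doxycycline pair the median was 0.0181 for genes over 200 kb and 0.0176 for the rest, a relative shift of 0.000557. This is within 0.106 of the smallest shift of the pairs. That bound could be passed only if the long genes rose with doxycycline, so it could not count an absent shift against this cause. The doxycycline pair showed no fall of long genes, but it has no replicate. With an estimated correlation, camera gave p = 0.0177 for the long genes without the block and 0.0855 with it, so an effect of dexrazoxane on transcription through long genes may be worth a test and is not shown here.

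TOP2A fell furthest of the genes called under dexrazoxane, in a line where its expression is set by tetracycline. A single misread probe set is argued against by the other probe set, which changed by -1.76. Fewer dividing cells as the whole cause stays open. TOP2A lay below the lowest of the 30 G2/M genes (CCNA2 or CENPE) in each pair, by -0.501 in the pair with the smallest gap, beyond its SE of 0.12. But it was picked as the gene that fell furthest, so that outcome was nearly given. With its expression set by tetracycline, the G2/M genes do not tell how far it would fall with fewer dividing cells. Tetracycline reaching the dexrazoxane cultures cannot be told apart from an effect of the drug on TOP2A transcripts, since the treated arrays stayed at least 4.50 above the doxycycline array, which a small dose could also give. A loss of transcript in response to dexrazoxane itself was not tested.

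The doxycycline differences followed pair 1 of the dexrazoxane arrays more than the others. Both arrays of that pair, treated and vehicle, were closer to both arrays of the doxycycline pair (r = 0.989 to 0.993) than those of pairs 2 and 3 were (0.977 to 0.982). The likeness was thus not confined to the vehicle arrays, but the 2 vehicle arrays were the most alike (0.993). The other combinations lay at 0.989 to 0.990. Noise of dim genes is argued against, since the correlation with pair 1 was 0.354 among genes above the 60th percentile. A vehicle sample shared between these pairs stays open: in a model with both deviations of pair 1 from its groups, the coefficient of the vehicle array was -0.170 and that of the treated array 0.195, close in size, and genes are too dependent on each other to rank them. A response common to TOP2A loss and dexrazoxane cannot be decided from pairs 2 and 3. Their correlations without TOP2A (0.0819 and 0.105) were above 0, which a weak response could give. They lay under the highest same-group value of 0.172, a bound written after the result was seen. That value comes from dexrazoxane arrays 1 and 2, which differ in number too and include the treated array of pair 1. The same-direction shares of called genes (80.7% against 54.3% and 63.5% against 40.8%) go with such a response. They rest on all 3 pairs, pair 1 included.

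The 6 dexrazoxane and vehicle arrays can be split in 10 ways, too few for a share under 0.05. Without the block the real split called 0 genes and the highest other split 0, so 10 of 10 were as large. For the gene lists 8 of 10 splits gave at least the real count of 4, with 9 the highest of the others; the other 3 splits that part all 3 pairs gave 2, 6 and 4 lists. Of the 4 splits that part all 3 pairs, 1, the real one, gave 717 genes in the paired fit and the highest other gave 0; the remaining 6 splits part 1 pair and also gave 0.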
